A study of Rattus norvegicus with 5 samples.

How the data were processed

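The samples were total RNA from proximal tubular cells, the epithelial cells of the first segment of the nephron, isolated from the kidneys of Sprague-Dawley rats with type I diabetes. Per the labels' protocols, the cells were kept for 2 h with or without C-peptide, the connecting peptide that is cleaved from proinsulin. RNA was extracted, amplified, converted to biotin-labelled sense-strand cDNA and hybridised to an Affymetrix whole-transcript array, per the labels' protocols. There were 5 arrays, 3 from C-peptide-treated cells and 2 from untreated cells, and the labels give each array of a group its own animal. Whether animal 1 of the treated group is also animal 1 of the untreated group is not given in the sources used here, and neither is a scan date or batch.

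The deposited values are probe-set intensities on a linear scale, made with the PLIER summary of Affymetrix Expression Console 1.1, per the submitters' processing notes. The background correction, the scaling between arrays and the filters that the authors used are not given in the sources used here. The deposited intensities lie at or above 0, and 550 of them are exactly 0. The array medians ranged from 60.1 to 95.9, so that the table had not been brought to 1 distribution across arrays. The plan fixed before the data were examined took the values as deposited, on the assumption that the authors had normalised them. That plan was kept for the stated tests, and the value after quantile normalisation is given beside the results it leads with. Every column of the table belonged to a sample.

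The 29215 probe sets were named through the platform annotation, with symbols updated through a current RefSeq gene table of the rat (assembly GRCr8), in which 15279 of the probe sets with a single symbol were found. A single gene symbol was paired with 15310 probe sets, several symbols with 323 and none with 13582. Probe sets with several symbols or none were tested and not named. The genome build of the array design is not given in the sources used here, so no coordinates are printed.

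Intensities were taken to log2(value + 16), and a fold on this scale understates the change of dim probe sets. The groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with group as the only term and Benjamini-Hochberg adjustment over all probe sets. The median difference of all probe sets, C-peptide minus untreated, was -0.13 in the values as deposited and 0.02 after quantile normalisation. Differences are therefore given relative to that median, while the p-values test the difference before the median was taken off. The difference after quantile normalisation is given as fitted. The number of arrays limits the precision of each value.

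A gene was represented by its brightest probe set, which left 14506 genes. The rule for the genes to be named was fixed before the data were examined. It took 12 genes in each direction, first those past adjusted p 0.05 whose treated arrays all lay beyond all untreated arrays, by size. A direction with fewer was filled by unadjusted p among genes without overlap that were brighter than the median probe set and differed by at least 1.3-fold. It also took up to 4 members of each gene list with the smallest p, and single markers of the cells studied. Part of what the rule took is not reported here. Other genes are said to have been chosen after their values were seen.

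Gene lists for pathways, for the tissue and for other cell types that the isolated cells could hold were also fixed before the data were examined, 29 in all. Each was tested with camera of limma at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. For members, the adjustment was made over all probe sets and also over the list alone.

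The scripts were tested on simulated arrays of 29215 probe sets with the spread of these data, in which 50 probe sets brighter than the median were changed at each of 4 fold sizes. With the array medians as deposited and no normalisation, 36% of the 2-fold and 100% of the 4-fold changes were called at adjusted p 0.05, along with 112 unchanged probe sets. Quantile normalisation of the same simulated arrays gave 30%, 90% and 8 unchanged probe sets. With camera at its preset correlation, a shifted gene list was called in each simulation, and 0 of 40 unshifted lists were. Simulated probe sets were drawn independently, so this cannot show how often lists of correlated genes are called falsely. The correlation estimated for the measured endothelial list was 0.90.

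The alternatives planned beforehand were quantile normalisation, centring each array on its median, other pseudocounts, filters on dim probe sets, 1-symbol probe sets alone, a trended and robust variance prior, array weights, other thresholds, the animal number as a block, other set tests, the mean of a gene's probe sets and leaving out each array in turn. Quantile normalisation together with array weights, with the trended prior or without the dimmest array was added after the data had been seen.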

Results

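Gene expression was measured in proximal tubular cells isolated from diabetic rats and either treated with C-peptide for 2 h, on arrays from 3 animals, or left untreated, on arrays from 2 animals. Each array gave 29215 probe-set intensities. The median intensity was 60.1, 95.9 and 77.7 on the arrays of C-peptide animals 1, 2 and 3, and 92.2 and 84.4 on those of untreated animals 1 and 2. After quantile normalisation, log2 values correlated across probe sets with Pearson's r of 0.970 to 0.982 between arrays of 1 group and 0.958 to 0.982 between arrays of different groups. The array of C-peptide animal 2 was as close to that of untreated animal 2 (r = 0.982) as to that of C-peptide animal 3 (r = 0.982). The single comparison, C-peptide against untreated, asks how C-peptide changes transcription within hours.

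**Figure D1:**
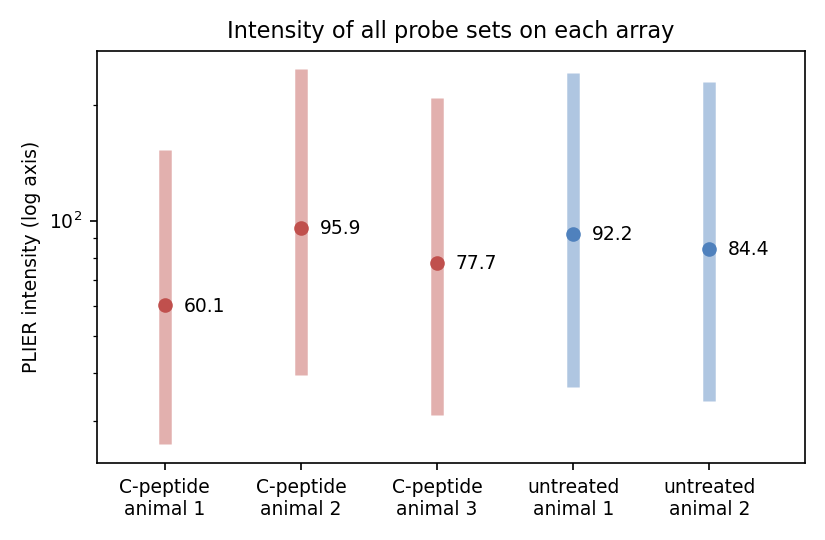
Intensity of all probe sets on each of the 5 arrays, on a log axis. Points are medians and bars run from the 25th to the 75th percentile; the array of C-peptide animal 1 had the lowest median, 60.1, and the other 4 lay between 77.7 and 95.9.

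As lists, endothelial markers and interferon response genes were lower in the C-peptide-treated cells and proximal tubule genes higher, all past camera, though at adjusted p = 0.524, 0.507 and 0.533 with an estimated correlation. Kap, the kidney androgen-regulated protein of the proximal tubule, rose 5.45-fold relative to the median probe set, from an intensity of 127 ± 6.84 (SD, n = 2) to 748 ± 352 (SD, n = 3). Cyp26b1, which degrades retinoic acid, fell 6.23-fold, from 404.8 ± 125 to 46.6 ± 20.4. The 11 measured endothelial markers were lower by a median of 2.30-fold, and 10 of them passed adjusted over the list alone, all but Plvap (-0.21), whose groups overlapped. The 35 measured transporters and markers of the proximal tubule itself had a median 1.35-fold higher, with none past adjusted p 0.05 alone.

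Among the genes higher with C-peptide, 4 passed at adjusted p 0.05 in limma. Beside Kap (log2 difference 2.45 ± 0.33, SE; adjusted p = 0.0145), these were Cyp2d2, a cytochrome P450, at 1.79 ± 0.28 (adjusted p = 0.0257), Ly6i, of the Ly6 family of surface proteins, at 1.69 ± 0.27 (adjusted p = 0.0390), and F3, tissue factor, which starts coagulation, at 1.68 ± 0.29 (adjusted p = 0.0408). After quantile normalisation they differed by 2.52, 1.86, 1.73 and 1.75, at adjusted p values of 0.0955 to 0.122. The next 8 genes by the naming rule did not pass. They were Hmox1, heme oxygenase, at 1.36 ± 0.27 (adjusted p = 0.0651), Slc5a8, a monocarboxylate transporter, at 1.34 ± 0.29, Ugt2b35, a glucuronosyltransferase, at 1.34 ± 0.30, and Fga, the fibrinogen alpha chain, at 1.27 ± 0.28. Cyp24a1, which inactivates vitamin D, had a log2 difference of 1.22 ± 0.27, Slc7a13, an amino acid transporter of the late proximal tubule, 1.17 ± 0.27, Slc22a2, an organic cation transporter, 1.07 ± 0.28 and Ppic, a cyclophilin, 1.06 ± 0.27. As the naming rule required, each of the 3 C-peptide arrays lay above both untreated arrays in all 12.

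Among the genes lower with C-peptide, Cyp26b1 had a log2 difference of -2.64 ± 0.31 (adjusted p = 0.000874) and -2.61 after quantile normalisation. Zbtb16, a zinc finger transcription factor, fell by 2.12 ± 0.34 (adjusted p = 0.0145), Sox18, a transcription factor of endothelial cells, by 2.09 ± 0.37 (adjusted p = 0.0257) and Mx2, an interferon-induced GTPase, by 2.04 ± 0.36 (adjusted p = 0.0257). Efnb2, an ephrin of arterial endothelium, was at -1.77 ± 0.38, and Klf4, a transcription factor, at -1.70 ± 0.34 with a further probe set at -1.87. Nkg7, a granule protein of natural killer and T cells, was at -1.67 ± 0.29, Dlc1 at -1.53 ± 0.31 and Rasip1, a Ras-interacting protein of endothelium, at -1.53 ± 0.33. Sh2d3c, Tmem26 and Ehd3 were at -1.51 ± 0.32, -1.50 ± 0.31 and -1.50 ± 0.32. These 8 genes had adjusted p values from 0.0257 to 0.0495. By the same rule, each C-peptide array lay below both untreated arrays in all 12, and after quantile normalisation none passed.

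**Figure D2:**
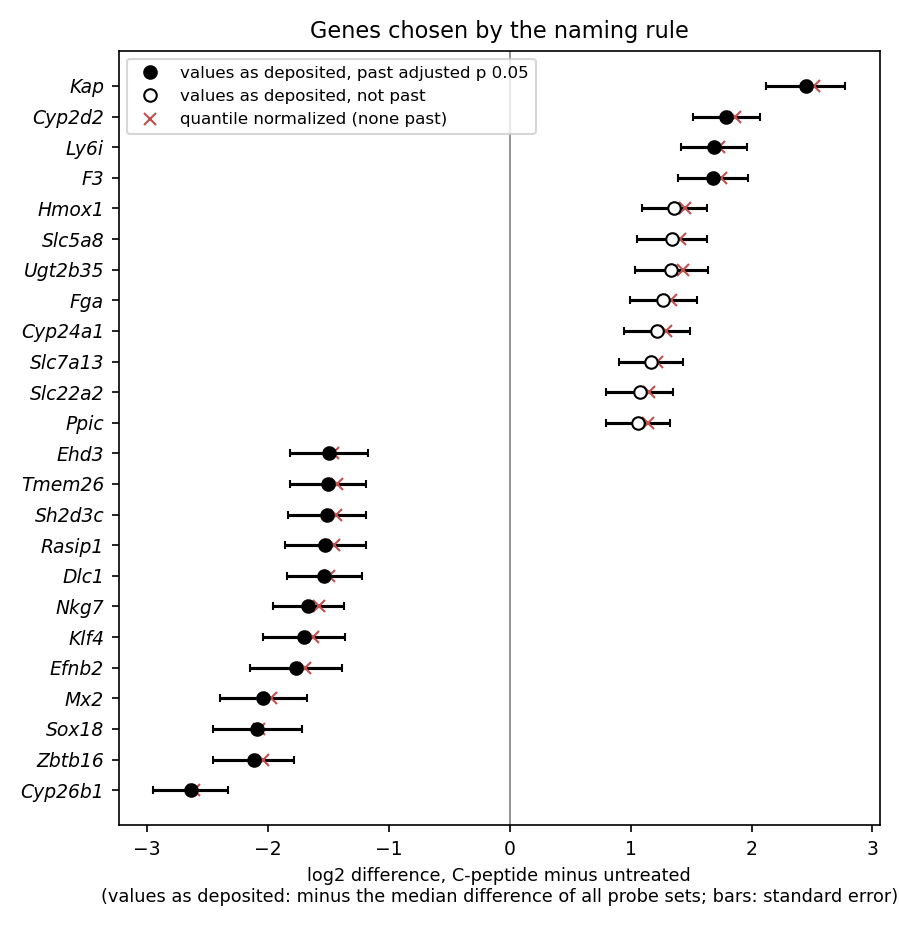
The 12 higher and 12 lower genes of the naming rule, as log2 differences of C-peptide minus untreated cells (3 against 2 arrays). Circles are values as deposited relative to the median of all probe sets, with bars of 1 standard error, filled where the gene passed adjusted p 0.05; crosses are the differences after quantile normalisation, where none passed, and run from -2.61 for Cyp26b1 to 2.52 for Kap.

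In all, 52 probe sets passed at adjusted p 0.05, 6 higher and 46 lower, and all of them separated the groups without overlap. They named 38 genes, 4 higher and 34 lower, with Klf4 and a predicted locus by 2 probe sets each, while 12 probe sets had no symbol here. At unadjusted p under 0.05 there were 2058, where 1460.75 would be expected by chance, and 1984 of these differed by at least 1.5-fold, 178 higher and 1806 lower. Quantile normalisation left 0 past adjusted p 0.05 in limma, with 3321 at unadjusted p under 0.05 (1478 higher, 1843 lower), and centring the arrays left 29 (7 higher, 22 lower), 25 of them among the 52. All 52, chosen on these same arrays at a stricter threshold, kept their sign at unadjusted p under 0.05 under both. The lower share of the 1.5-fold probe sets was 91.0% in the values as deposited, 68.8% after quantile normalisation and 65.9% after centring. Groups did not overlap in 20.7% of all probe sets, and in 28.9% once arrays were centred, where chance gives 20%. The count rested on single arrays, at 0, 515 and 166 without C-peptide animals 1, 2 and 3 and 13 and 181 without untreated animals 1 and 2, and simulated arrays with the deposited medians gave 112 calls among unchanged probe sets.

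Markers of endothelial cells, which line blood vessels and would be a second cell type in a tubular preparation, stood lowest of the 29 gene lists. Ehd3, a marker of glomerular endothelium, fell 2.82-fold relative to the median probe set, from an intensity of 2474 ± 396 to 837 ± 374. Tek, the angiopoietin receptor, was at a log2 difference of -1.30 ± 0.31, Tie1 at -1.25 ± 0.31 and Flt1, a VEGF receptor, at -1.17 ± 0.30. Of the 11 measured, 1 passed over all probe sets and 10 adjusted over the list alone, all lower. The list's median log2 difference was -1.20, and -1.15 after quantile normalisation. In camera the adjusted p was 3.71e-26, and the adjusted p was 0.524 with an estimated correlation.

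Markers of podocytes, the epithelial cells of the glomerular filter, had a median of -0.55 over 6 genes, -0.34 without untreated animal 1 and -1.22 over the 3 genes above the median intensity. Adjusted over the list alone 3 of them were lower and over all probe sets 0, namely Podxl (-1.34 ± 0.33) and Clic5 (-1.27 ± 0.33), which endothelial cells also express, and Synpo (-0.70 ± 0.28). Nphs1, nephrin of the slit diaphragm, was at 0.12, a value chosen after it was seen. The list's adjusted p was 1.67e-05 in camera and 0.533 with an estimated correlation. Immune cell markers had a median of -0.45 over 17 genes, with 0 past over all probe sets or adjusted over the list alone, although 12 passed adjusted over the list alone without C-peptide animal 2. Laptm5 (-0.72 ± 0.29) and C1qc (-0.82 ± 0.33) had the smallest p among them. Camera gave this list an adjusted p of 8.43e-07, with an adjusted p of 0.595 at an estimated correlation. Thick limb and distal tubule markers lay the other way, with a median of 0.34 over 11 genes and Slc12a3, the thiazide-sensitive cotransporter, at 0.64 ± 0.30, none past either adjustment. That median was 0.20 and 0.22 without C-peptide animals 2 and 3. Their adjusted p was 0.00730 in camera and 0.781 with an estimated correlation, and in camera 0.144 without C-peptide animal 2. Medians were 0.11 for collecting duct, -0.03 for stromal and smooth muscle and -0.07 for red blood cell markers, and none of these lists was called. The collecting duct list was called as higher after quantile normalisation (adjusted p = 0.0394), without C-peptide animal 1 (adjusted p = 0.000476) and without untreated animal 1 (adjusted p = 0.0103). With an estimated correlation its adjusted p was 0.896, and 0.555 after quantile normalisation.

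**Figure D3:**
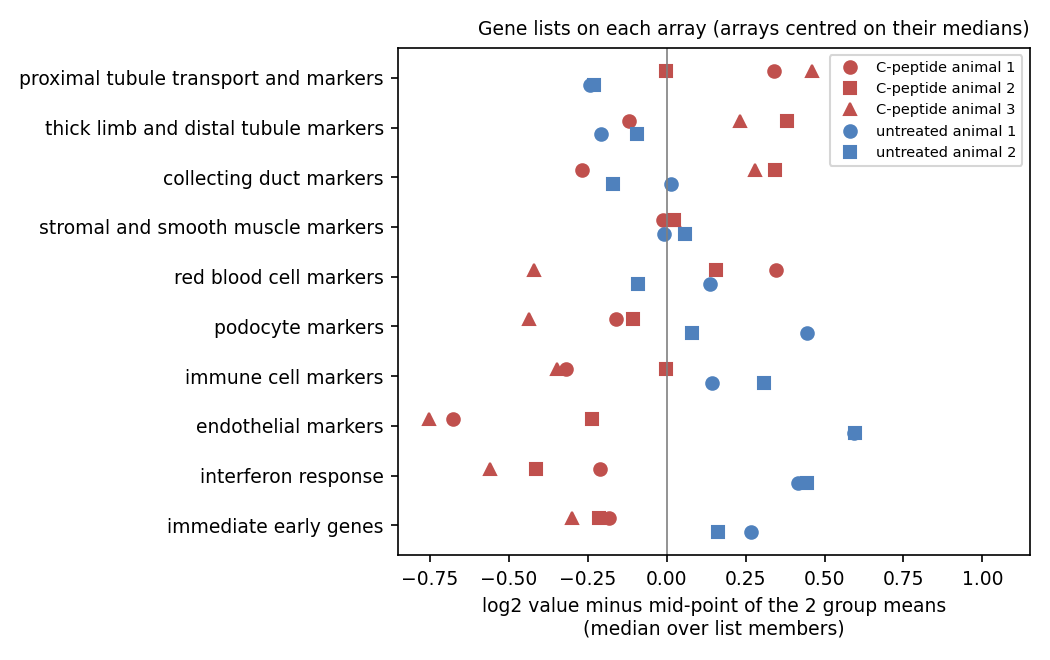
For 10 gene lists, the median over the members of the log2 value on each array, centred on the array's median, minus the mid-point of the 2 group means. Endothelial markers lay at -0.68, -0.24 and -0.75 on the C-peptide arrays and at 0.59 and 0.60 on the untreated arrays, and proximal tubule markers at 0.34, -0.00154 and 0.46 against -0.24 and -0.23.

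Genes of the interferon response, an antiviral programme, were lower with C-peptide. Ifit2 was at -1.18 ± 0.28, Oas1a at -1.16 ± 0.27 and Usp18 at -1.10 ± 0.27, after Mx2. Of the 16 measured, Mx2 passed over all probe sets and 12 passed adjusted over the list alone, all lower, while Ifit1 was at 0.25. The median was -0.91, and -0.82 after quantile normalisation, beside -1.20 for endothelial and -0.45 for immune cell markers on the same arrays. For the interferon list the adjusted p was 9.72e-22 in camera, and the adjusted p = 0.507 with an estimated correlation.

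Immediate early genes, which cells switch on within an hour of a stimulus and many of which encode transcription factors, were mostly lower after 2 h of C-peptide. Klf2, a transcription factor that blood flow induces in endothelium, was at -1.49 ± 0.38, Nr4a3 at -0.98 ± 0.29 and Junb at -0.83 ± 0.28, after Klf4. Of the 28 measured, Klf4 passed over all probe sets and 15 were lower adjusted over the list alone, a count that was 0 at a pseudocount of 1, 6 without C-peptide animal 3, 2 without untreated animal 1 and 5 without untreated animal 2. The median was -0.58, beside -1.20 for endothelial markers, and -0.57 after quantile normalisation, with Myc (0.63) and Maff (0.48) on the other side of 0. For immediate early genes the adjusted p was 3.63e-10 in camera and 0.533 with an estimated correlation.

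Further lists were lower on the arrays where endothelial markers had a median of -1.20. Feedback regulators of the ERK pathway had a median of -0.49 over 16 genes. Phlda1 was at -1.04 ± 0.26, Dusp8, a MAP kinase phosphatase, at -0.87 ± 0.28, and Errfi1, an inhibitor of the EGF receptor, at 0.84. Adjusted over the list alone 6 were lower and 1 higher, over all probe sets 0. The lower count over the list was 3 after quantile normalisation, 0 at a pseudocount of 1, 2 without C-peptide animal 3, 0 without untreated animal 1 and 2 without untreated animal 2, and in the last 4 of these none was higher. The ERK list's adjusted p was 2.82e-05 in camera and 0.595 with an estimated correlation. CREB targets had a median of -0.40 over 15 genes, with 5 lower adjusted over the list alone (Nr4a3, Nr4a1, Nr4a2, Rgs2 and Fos, of which all but Rgs2 are also immediate early genes) and 0 over all probe sets. Their count over the list was 0 at a pseudocount of 1 or of 64, 1 without C-peptide animal 1, 0 without untreated animal 1 and 3 without untreated animal 2. The CREB list's adjusted p was 6.52e-05 in camera and 0.595 with an estimated correlation. NF-kB targets had a median of -0.25 over 20 genes, with Nfkbiz (-1.04 ± 0.30), the chemokine Ccl2 (-0.76 ± 0.26) and Cxcl2 (-0.68 ± 0.26) lower adjusted over the list alone and 0 past over all probe sets. That count was 1 after quantile normalisation, 0 at a pseudocount of 1, 5 without C-peptide animal 2, 1 without C-peptide animal 3, 0 without untreated animal 1 and 1 without untreated animal 2. Their adjusted p was 0.0136 in camera and 0.595 with an estimated correlation. In camera it was 0.144, 0.0640 and 0.0574 without C-peptide animal 2, C-peptide animal 3 and untreated animal 2.

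The list of the TGF-beta response and matrix had a median of -0.28 over 20 genes, on arrays where endothelial and immune cell markers had medians of -1.20 and -0.45. Bmp2, a growth factor of the TGF-beta family, fell by 1.42 ± 0.29 on the log2 scale (adjusted p = 0.0410). Smad6, an inhibitor of BMP signalling, was at -1.53 ± 0.36, Ltbp1 at -1.24 ± 0.33 and Tgfb1 at -1.03 ± 0.31. Bmp2 passed over all probe sets and 5 genes adjusted over the list alone, 1 at a pseudocount of 1, 9 without C-peptide animal 2 and 3 without untreated animal 1. Of the 20 members, 15 lay below 0, and the collagens Col1a1 and Col1a2, named after their values were seen, were at 0.10 and 0.01. The TGF-beta list's adjusted p was 5.07e-08 in camera and 0.595 with an estimated correlation. On the same arrays the cell cycle list had a median of -0.15 over 18 genes and -0.50 over the 8 above the median intensity, with Ccnd2 (-0.88 ± 0.27), Pcna (-0.71 ± 0.26) and Cdkn1a, an inhibitor of the cycle (-0.67 ± 0.27), lower adjusted over the list alone and 0 past over all probe sets, 1 over the list after quantile normalisation, 5 without C-peptide animal 2 and none without C-peptide animal 3 or either untreated animal, or at a pseudocount of 1. Its adjusted p was 0.0238 in camera and 0.795 with an estimated correlation, and in camera 0.122 without C-peptide animal 2 and 0.0724 without untreated animal 2.

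Genes of the proximal tubule's own transport were higher as a list, with a median of 0.44 over 35 genes and 34 of them above 0. Thick limb and distal markers had a median of 0.34 on the same arrays, and endothelial and immune cell markers -1.20 and -0.45. Slc22a6, an organic anion transporter, was at 0.94 ± 0.29, Lrp2, the endocytic receptor megalin, at 0.84 ± 0.28 and Slc17a3 at 0.83 ± 0.29. None passed over all probe sets or adjusted over the list alone in the values as deposited, while 13 were higher over the list alone after quantile normalisation and 10 without C-peptide animal 1. The adjusted p was 1.63e-15 in camera and 0.533 with an estimated correlation. As single markers of the cells, Aqp1 was at 0.52 ± 0.27 and Slc5a2, the glucose transporter of the early proximal tubule, at 0.33 ± 0.26, neither past the test. Atp1b1, a subunit of the sodium pump, was at 0.18 ± 0.28 (0.04 after quantile normalisation).

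Antioxidant genes were higher as a list, with a median of 0.22 over 20 genes and 0.33 over the 17 above the median intensity. On the same arrays proximal tubule genes had a median of 0.44, thick limb and distal markers 0.34 and endothelial markers -1.20, beside this list and the next 3. Hmox1 (from 206.7 ± 15.3 to 513 ± 114) and Osgin1 (1.01 ± 0.27) were higher adjusted over the list alone, 0 over all probe sets. Without C-peptide animal 1 this count was 3, without C-peptide animal 3 or untreated animal 1 it was 1, and without untreated animal 2 or at a pseudocount of 1 it was 0. The antioxidant list's adjusted p was 7.86e-06 in camera and 0.533 with an estimated correlation. Gluconeogenesis had a median of 0.32 over 14 genes (0.21 without untreated animal 1), with Pc, pyruvate carboxylase, at 0.67 ± 0.26, and 0 past either adjustment. Its adjusted p was 0.00130 in camera and 0.595 with an estimated correlation. Fatty acid oxidation and PPAR targets had a median of 0.19 over 27 genes, with Cyp4a8 at 1.05 ± 0.28. The gene of that list that passed adjusted over the list alone in the values as deposited was lower, Ucp2, a mitochondrial carrier (-1.52 ± 0.35), with 0 past over all probe sets, while after quantile normalisation, and after centring, 2 were higher and 1 lower, and at a pseudocount of 1 none was either. The adjusted p was 0.00858 in camera and 0.665 with an estimated correlation. Respiratory chain genes had a median of 0.14 over 24 genes (0.02 without untreated animal 1 and 0.25 without untreated animal 2), with Ndufs1 at 0.44 ± 0.26 and 0 past either adjustment. Their adjusted p was 0.0410 in camera and 0.896 with an estimated correlation, and in camera 0.0525, 0.134 and 0.478 without C-peptide animal 1, C-peptide animal 3 and untreated animal 1.

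Of the other lists, none was called in the values as deposited. Vasoactive and G-protein-coupled systems had a median of -0.17 over 28 genes, with Nos3, the endothelial nitric oxide synthase, lower adjusted over the list alone (-1.12 ± 0.29), though not without C-peptide animal 1 or untreated animal 1 or at a pseudocount of 1, and the list was called as lower without untreated animal 2 (adjusted p = 0.0211). With all arrays and an estimated correlation its adjusted p was 0.896, and 0.532 after quantile normalisation. The heat shock response had a median of -0.15 over 14 genes, with Hspb1 lower adjusted over the list alone (-1.39 ± 0.35), though not without C-peptide animal 1 or at a pseudocount of 1 or 64, and with 3 such genes without C-peptide animal 2. Sodium pump subunits and regulators had a median of 0.00380 over 14 genes, a mean of -0.12 and a camera direction of lower (adjusted p = 0.394), with Fxyd5 at -0.68 ± 0.30. Medians were 0.16 for cholesterol synthesis, 0.10 for tubular injury and dedifferentiation, 0.03 for hypoxia response and glycolysis, -0.02 for the unfolded protein and integrated stress response, -0.04 for the insulin and FOXO response, -0.07 for the circadian clock and -0.17 for ribosomal proteins. After quantile normalisation the lists of cholesterol synthesis (adjusted p = 0.0394) and ribosomal proteins (adjusted p = 0.0191) were called, as they were without C-peptide animal 1 (adjusted p = 0.0272 and 0.00571) and, for ribosomal proteins, without untreated animal 1 (adjusted p = 6.94e-05). With quantile normalisation and an estimated correlation their adjusted p was 0.527 and 0.567. With camera 16 of the 29 lists passed, 6 higher and 10 lower, 19 did after quantile normalisation, and with an estimated correlation 0 did, 2 of them at unadjusted p under 0.05.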

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

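The 3 settings that join quantile normalisation to another step were chosen after the data had been seen, and all others were planned. The count of probe sets past adjusted p 0.05, 52 in the values as deposited, moved by over 1.5 times under each alternative that was run. In limma it was 0 after quantile normalisation (3321 at unadjusted p under 0.05), 0 with that and array weights (3707), 0 with that and without the array of C-peptide animal 1 (3251), 208 with that and a trended, robust variance prior, and 29 with arrays centred on their medians. It was 4 at a pseudocount of 1, 0 at a pseudocount of 64 (1917 at unadjusted p under 0.05), 513 and 457 for probe sets above the 25th percentile and above the median, 438 for probe sets with 1 gene symbol, 530 with the trended prior, 237 at adjusted p under 0.1 and 8163 with array weights, which gave C-peptide animal 3 a weight of 436.5 and C-peptide animal 1 a weight of 0.0731. Leaving out single arrays gave 0 to 515. The cause of these moves was not tested, except that unequal array medians alone gave 112 calls among unchanged probe sets in simulated arrays, against 8 once these were quantile normalised. All 52 kept their sign at unadjusted p under 0.05 in each setting that tested them, with 49, 47 and 40 of them left by the 25th percentile, the median and the single symbol. As the 52 were chosen on these same arrays at a stricter threshold, that they kept their sign carries little weight. The 1984 probe sets at unadjusted p under 0.05 and 1.5-fold became 941 at a pseudocount of 64, 1266 with 1 gene symbol, 3298 with array weights, 1292 with quantile normalisation and array weights and 500 at 2-fold, the last by its own construction. Leaving out single arrays gave 924 (without untreated animal 1) to 3838 (without C-peptide animal 2). Where 1 array was left in a group, it was assumed to vary like those of the other group. The 16 gene lists stayed between 13 and 19 in the other settings, and were 0 with an estimated correlation, where gene-to-gene correlation within the list is allowed for, and 0 with fry. Neither camera with an estimated correlation nor fry was tried on the simulated arrays. With 3 arrays against 2, a list that passes neither is not shown to be unchanged. The respiratory chain turned from higher to lower with fry, at an adjusted p of 1.00. List medians kept their side of 0 in each of the 19 settings for all 16 called lists, from -1.43 to -1.10 for endothelial markers, -1.11 to -0.71 for interferon response, -0.59 to -0.40 for immediate early genes and 0.32 to 0.66 for proximal tubule genes. These medians are relative, so centring repeats the main values by construction, and the trended prior those of the fit it is added to. The replicate block repeats the values without C-peptide animal 3. The 0.66 came from array weights, where C-peptide animal 3 had a weight of 436.5. As the lists were called on these same arrays, that their medians kept their side of 0 is no separate support. At a pseudocount of 64 the median was -0.07 for the cell cycle and 0.08 for the respiratory chain, which array weights put at 0.21. Counts of lower genes over the list alone were 22, 13, 12, 10, 11 and 8 with array weights for immediate early, ERK, NF-kB, CREB, TGF-beta and cell cycle genes, and 6, 2, 1, 4, 5 and 0 with the animal number as a replicate block. Medians of each list that was not called moved by over 1.5 times in some setting.

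The labels number the animals 1 and 2 in both groups without saying that a number is shared. The deviations of same-numbered arrays from their group means correlated across probe sets at -0.0250 for number 1 and 0.00790 for number 2, over a pair each. With 2 untreated arrays their deviations mirror each other, so both values use the same untreated deviations. They are not separate checks and cannot settle whether the animals were paired. With the animal number as a replicate block, 79 probe sets passed adjusted p 0.05, 35 of them among the 52, and 14 gene lists passed. The array of C-peptide animal 3 has no partner and drops out of that comparison.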

Other observations

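The tests of array scale, and of a dilution that reaches all other cells alike, were chosen after the results they bear on had been seen.

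A further 3 of the genes that fell with C-peptide were picked after their values were seen. Csf1, the growth factor of macrophages, fell 2.38-fold relative to the median probe set, from 361.6 ± 37.9 (SD, n = 2) to 130.7 ± 33.8 (SD, n = 3), and Ccl5, a chemokine, fell 2.39-fold, from 935.9 ± 34.7 to 348 ± 24.0. Apold1, an early response gene of endothelium, fell 2.51-fold, from 1515 ± 80.3 to 541 ± 37.8. All 3 passed adjusted p 0.05 in limma in the values as deposited, and none did after quantile normalisation. All 3 were lower on each C-peptide array than on either untreated array, as were all 46 lower probe sets that passed.

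A further list of 18 endothelial genes, none on the list reported above, was written down before its values were seen. The results of the first list were known by then. Of the 18 genes, 16 were lower, though genes of 1 cell type on the same arrays are no independent test of each other. Sox18 (-2.09 ± 0.37) and Rasip1 (-1.53 ± 0.33) passed over all probe sets, and Sox17 (-1.55 ± 0.39), Aplnr (-1.46 ± 0.43), Ramp2 (-1.41 ± 0.34) and Eng (-1.26 ± 0.34) did not. Gpihbp1 and Cldn5 lay on the other side, at 0.19 ± 0.29 and 0.18 ± 0.26. Of the 38 genes named by the called probe sets, 3 were on either endothelial list, which together hold 29 of the 14506 genes measured. The lists do not hold every endothelial gene: Efnb2 and Apold1, described above as genes of endothelium, are on neither. The 3 are therefore not a count of all endothelial genes among the 38. Among proximal tubule genes, 7 markers of the late, straight segment had a median of 0.66 after quantile normalisation and 7 of the early segment 0.37, all 14 above 0. Slc15a2, a peptide transporter of the late segment, was at 0.72 ± 0.27 and Slc5a12, a lactate transporter of the early segment, at 0.38 ± 0.27, neither past the test.

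Endothelial markers were lower and proximal tubule markers higher with C-peptide. Array scale as the cause is argued against by its size. The median difference of all probe sets was -0.13, and the endothelial median lay at -1.20 relative to it. Correcting for scale was therefore not likely to remove the fall. The endothelial median after quantile normalisation, -1.15 with a standard deviation of 0.36 over members, is thus no separate test. An even dilution of all other cells is argued against by the thick limb and distal markers, which lay 1.56 above the endothelial ones. The two-sided permutation test over genes (p = 0.00064) took genes as independent. Members moved together, at estimated correlations of 0.81 (thick limb and distal) and 0.90 (endothelial), so this p does not measure variation between animals. Centred on array medians and the mid-point of the groups, thick limb and distal markers lay at -0.12, 0.38 and 0.23 on the C-peptide arrays. On the untreated arrays they lay at -0.21 and -0.09, so C-peptide animal 1 was within the untreated range. Fewer endothelial cells in the treated samples may account for the pattern. The further endothelial list, written with the fall of the first list known and measured on the same arrays, had a median of -1.07 after quantile normalisation. An effect of C-peptide on transcription inside endothelial cells would give the same values and was not tested. How many of these genes tubular cells also express was not measured here.

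Immediate early genes were lower with C-peptide. Array scale as the cause is argued against by its size, as all probe sets had a median difference of -0.13 and these genes lay at -0.58 relative to it. Their median of -0.57 after quantile normalisation is no separate test of it. Fewer endothelial cells in the treated samples stay open. That 0 of the 28 immediate early genes lay below the lowest of 29 endothelial genes (-2.07 after quantile normalisation, Sox18) decides nothing, since that bound is a single extreme. A response of the tubular cells to C-peptide is open too.

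Kap, Cyp2d2 and Slc7a13 were higher with C-peptide in the values as deposited, at adjusted p = 0.0145, 0.0257 and 0.111 in limma. Slc7a13 thus did not pass, and after quantile normalisation none of the 3 did (adjusted p = 0.0955 each). They are no list fixed beforehand but part of the 12 higher genes of the naming rule, leaving out Ly6i and F3, which passed. Array scale ran opposite to these rises, as the median difference of all probe sets was -0.13 in the values as deposited. Correcting for it was therefore not likely to remove them. That the smallest of the 3 log2 differences was 1.22 after quantile normalisation is no separate test of array scale. Animals of different sex in the groups stay open, since 0 of the Y-linked genes and Xist had a probe set of their own in the annotation used here, and Kap is known to follow androgens. More late than early proximal tubule in the treated samples may contribute, with late markers 0.29 above early ones, but the two-sided permutation test over genes (p = 0.114) does not decide it. An effect of C-peptide itself also stays open.

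The 5 arrays can be split into 3 and 2 in 10 ways, too few for a share under 0.05. The real split called 52 probe sets in the values as deposited, and of the 10 splits 2 called as many, itself and 1 other. That highest other, with 257 probe sets, set C-peptide animal 2 and both untreated animals against C-peptide animals 1 and 3. As it moves only C-peptide animal 2, it keeps most of the treatment contrast. It therefore cannot tell a structure of the arrays beside the treatment from the treatment itself. That split parts the arrays with the lowest medians (60.1 and 77.7) from the others, and after quantile normalisation none of the 10 splits called any, with 3321 probe sets at unadjusted p under 0.05 for the real split and 3043 for that one, against 2058 and 5882 in the values as deposited. Along the first principal component after quantile normalisation, with 43.0% of the variance, C-peptide animals 1, 3 and 2 lay at 41.8, 13.0 and 1.68 and untreated animals 2 and 1 at -21.5 and -35.0.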
